A study of Mus musculus with 4 samples.

How the data were processed

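Visium spatial gene expression was measured on fresh frozen kidney sections, cut at 10 µm, of 2 Uox_KO and 2 Control male mice. The deposited values are raw UMI counts per gene and spot, made by the authors with Space Ranger 1.3.1 against mm10, per the submitters' processing notes and the file headers. The counts are whole numbers. The files pair 32285 Ensembl gene IDs with symbols, and genes are named by those symbols. Genotype, sex, strain background and replicate come from the labels. File names carry other replicate numbers than the labels, and the labels were followed. The labels do not say which mice were litter mates, in which run each section was sequenced, or the age of the mice.

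Section totals were 93524222 and 107962997 UMIs in Control and 53897511 and 57230517 UMIs in Uox_KO, with 19166 to 19763 genes detected per section. The 10 most abundant genes took 22.5% and 23.2% of the UMIs in Control and 19.7% and 22.1% in Uox_KO. Where a gene had 0 counts, the limit given is 3 counts of the total, counting error only. A fold against a group at 0 was computed against 3 counts over the group and is a lower bound.

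UMI counts were summed over all spots of a section, and the section was the unit of every test, since spots of 1 section are not replicates. Genes were filtered with filterByExpr by genotype, scaled with TMM and tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test of Uox_KO against Control without covariates. Benjamini-Hochberg adjustment was over all genes tested in a comparison, with a threshold of 0.05. CPM use the TMM-scaled library sizes. Standard deviations are over 2 sections. A whole section also holds how much of each kidney zone was cut, so the same test was run within regions.

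For regions, spots with at least 500 UMIs were kept, which left out 1 spot. Genes other than mitochondrially encoded ones were scaled to 10000 UMIs per spot and log-transformed with scanpy 1.11.5. The 2000 most variable genes with the section as batch were z-scored within each section and clipped at 10. Leiden clustering (leidenalg 0.10.2) at resolution 0.5 with seed 0 ran on a graph of shared neighbours, from the 15 nearest of each spot in 30 principal components. A cluster took the class with the most markers among its 25 leading genes, with at least 3 markers needed, and a cluster without them went to the proximal class where its S1 and S2 marker levels were at least 0.5 of those of the other proximal clusters. The markers were fixed before the data were examined and this rule after. Proximal, distal, glomerular and injury regions were tested, each with at least 20 spots in every section. The fat region had too few Control spots and was not tested. Many leading genes of the clusters differ between genotypes, so the 10 leading genes of a cluster were not named one by one as results of the region they define. The results compare shares of spots only for a clustering made without the genes called in whole sections, and the differences in share of the other clusterings are given in the closing section only to show how far they depend on the clustering. Shares carry exact Clopper-Pearson 95% intervals, and the exact two-sided permutation test on 2 against 2 sections cannot go below 0.333.

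Whether the genotype difference differed between regions was tested in 1 edgeR fit of all tested regions with mouse as a block and a region by genotype term. Gene lists of 45 pathways, cell types and controls were fixed before the data were examined. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, and adjusted over the lists of each comparison. Beside it stands camera with the correlation estimated from the 4 sections, under which no list was called in any comparison. That version also rests on the few residual degrees of freedom of 4 sections. Its adjusted p thus does not show whether gene correlation undid a call. The fry test, which asks whether the genes of a list move on balance 1 way, was also run. Several lists share the tissue they describe, since the kidney itself expresses most listed tubule, glomerulus and vessel genes.

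The genes named were chosen by a rule fixed before the data were examined. It takes Uox and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 10 CPM and both Uox_KO sections on the same side of both Control sections. Predicted genes are counted and not named. It adds up to 4 members of each list with the smallest p, and further members of the urate transporter, purine, tubular injury and matrix lists. Genes outside the rule are marked as chosen after their values were seen. Coordinates are from the GRCm38 annotation.

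The pipeline was tested on simulated data made from the mean levels, section totals and gene dispersions of the real sections. It recovered 87 to 97% of genes changed 2-fold and 100% of genes changed 4-fold, with 6 to 31 false calls per comparison. A raised list was called and 0 of 19 unchanged lists were. For the gene counts 200 genes were changed per comparison, and genes were drawn independently of each other. In the real data 40.8 to 67.1% of the genes were called. The simulation thus does not test the scaling where most genes change, or the preset inter-gene correlation.

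Alternatives tried were DESeq2 1.42.0, RLE scaling, no low-count filter, leaving out mitochondrially encoded genes, leaving out each section in turn, the replicate number as a block, thinning all sections to the lowest total, spots with at least 2000 UMIs, and equal numbers of spots per region. Further ones were other cluster resolutions (0.3 and 0.8), no z-scoring within sections, and clustering without the genes called in whole sections. Whole sections without fat spots, and without fat and injury spots, were added after the data were seen. Not used here were tissue images and spot positions, so no distance between spots was measured. The listed symbols Nnt, Aldoa and Ddit3 each stand for 2 gene IDs in the files and Ctgf is not a symbol there, so these 4 were not analysed here. Some genes that the naming rule allows are not reported here.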

Results

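Spatial gene expression was measured with the Visium assay on kidney sections of male mice of the C57BL/6J background. The Uox_KO mice lack exons 2 to 4 of the gene for urate oxidase, the enzyme that degrades uric acid in rodents, and serve as a model of hyperuricemia. There were 2 Uox_KO sections and 2 Control sections, each from its own mouse by its title, and the section was the replicate (n = 2 per group). A Visium spot collects polyadenylated RNA from the tissue above it, usually from several cells. The Control sections held 2528 and 3362 spots with 93524222 and 107962997 unique molecular identifiers (UMIs). The Uox_KO sections held 2650 and 2590 spots with 53897511 and 57230517 UMIs. The median spot had 37386 and 32038.5 UMIs in Control and 16674 and 19599.5 UMIs in Uox_KO, so whole-section values of Uox_KO rest on fewer molecules. Mitochondrially encoded transcripts took 13.0% and 14.0% of the UMIs in Control and 14.3% and 17.3% in Uox_KO. Gene levels are given as the mean ± SD in CPM, the UMI counts scaled to the same library size, n = 2 sections per group.

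The transcript of the targeted gene, Uox (GRCm38 chromosome 3, 146597149 to 146631483), had 0 counts in all 4 sections. A count of 0 allows up to 0.0321 and 0.0278 CPM in the Control sections and up to 0.0557 and 0.0524 CPM in the Uox_KO sections, counting error only. Urate oxidase is mainly a liver enzyme, so the kidney level says nothing about the knockout.

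The comparison of whole sections asked which transcripts differ in the kidney of mice that cannot break down uric acid. In the Uox_KO sections, transcripts of damaged tubule cells, of collagen-producing stroma and of immune cells stood far above Control. Transcripts of mature S1 and S2 and thick limb segments, of nuclear-encoded respiration genes and of haemoglobin were lower. Of 16369 genes tested, 5665 were higher and 5325 were lower in Uox_KO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. More than 2-fold, 3225 genes were higher and 1253 were lower, and more than 4-fold, 1841 were higher and 276 were lower. Both Uox_KO sections lay on the same side of both Control sections for 85.7% of the genes, where chance gives 33.3%. The p-values measure the spread between 2 sections per genotype.

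Markers of an injured tubule rose, some of them from under 1 CPM. Havcr1, which encodes the kidney injury molecule KIM-1, was 0.305 ± 0.00170 CPM in Control and 86.4 ± 9.03 CPM in Uox_KO (log2 fold change 8.14, adjusted p 4.4e-07). Lcn2, for the siderophore-binding protein lipocalin-2, was 0.339 ± 0.0361 CPM in Control and 92.8 ± 15.5 CPM in Uox_KO (adjusted p 1.1e-06). Timp1, an inhibitor of matrix proteases, went from 0.529 ± 0.0666 to 94.1 ± 1.25 CPM and the monocyte chemokine Ccl2 from 0.249 ± 0.0196 to 39.8 ± 1.62 CPM. The stress-induced growth factor Gdf15 went from 5.99 ± 0.0236 to 44.0 ± 1.15 CPM. The abundant secreted phosphoprotein Spp1 went from 525 ± 45.3 to 7317 ± 320.3 CPM. Of the 30 listed tubular injury genes, 29 were higher and 1 was lower, with a median log2 fold change of 2.74 (camera adjusted p 3.14e-11, and adjusted p 0.381 with an estimated correlation). The other genes with the largest rises are not all genes of the tubule. Sprr1a, a cornified envelope gene of stressed and stratified epithelia, was 0.0438 ± 0.00466 CPM in Control and 42.7 ± 3.60 CPM in Uox_KO, and 74.9% and 76.6% of its UMIs in the Uox_KO sections lay in spots of fat, which also held urothelial genes. Next were the macrophage genes Ccl8 at 0.0639 ± 0.0760 CPM in Control and 30.6 ± 15.3 CPM in Uox_KO and Fcrls with a log2 fold change of 8.05 (standard error 0.23, n = 2 per group), the matrix gene Ltbp2 at 0.144 ± 0.0539 CPM in Control and 72.1 ± 13.9 CPM in Uox_KO, Serpina10 at 0.0917 ± 0.0133 CPM in Control and 33.6 ± 8.18 CPM in Uox_KO and the adipocyte gene Cfd at 5.22 ± 5.49 CPM in Control and 976 ± 477 CPM in Uox_KO.

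**Figure D1:**
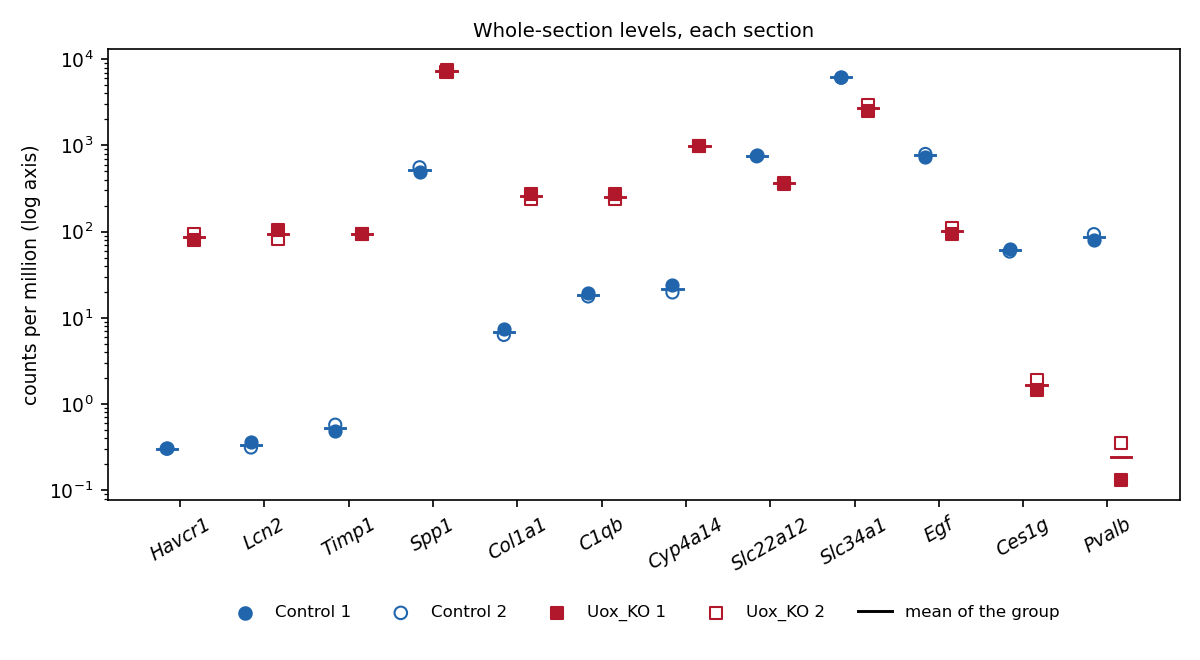
CPM of 12 genes in each whole section on a log axis, Control in blue circles and Uox_KO in red squares, with the mean of each group as a bar. The 2 Uox_KO sections lie above both Control sections for Havcr1, Lcn2, Timp1, Spp1, Col1a1, C1qb and Cyp4a14 and below them for the other genes.

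Transcripts of extracellular matrix and stroma rose along with the injury markers. How much of this rise came from stroma at the hilum and pelvis was not tested. All 29 tested genes of extracellular matrix and fibrosis were higher, with a median of 2.92 (camera adjusted p 3.14e-11, and adjusted p 0.618 with an estimated correlation). Col1a1, the chain of fibrillar collagen I, went from 6.86 ± 0.739 to 258 ± 26.4 CPM, the matricellular gene Sparc from 80.5 ± 0.827 to 608 ± 2.23 CPM and the gelatinase Mmp2 from 2.96 ± 0.161 to 29.4 ± 1.01 CPM. All 8 smooth muscle and pericyte genes were higher with a median of 1.28 (camera adjusted p 0.0131, and adjusted p 0.618 with an estimated correlation). Proliferation genes moved the same way, since all 18 cell cycle genes were higher with a median of 2.30 (camera adjusted p 2.00e-07, and adjusted p 0.495 with an estimated correlation), and Mki67 went from 1.07 ± 0.00951 to 14.2 ± 0.114 CPM.

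Immune genes of nearly every kind were higher, except those of B and plasma cells. All 26 macrophage and other myeloid genes were higher with a median of 3.34, among them the phagocyte gene Laptm5 (7.86 ± 0.623 to 95.4 ± 3.83 CPM) and the complement gene C1qb (18.5 ± 1.08 to 255 ± 24.1 CPM). The camera adjusted p was 1.95e-10, and the adjusted p with an estimated correlation was 0.618. Of 16 T and NK cell genes 15 were higher (median 2.58, camera adjusted p 1.76e-06, and adjusted p 0.495 with an estimated correlation), and Cd3e had a log2 fold change of 3.75 (standard error 0.16). Of 11 B and plasma cell genes 3 were higher and 2 lower, and the list was not called (adjusted p 0.882). All 30 interferon response genes were higher with a median of 1.61 (camera adjusted p 1.95e-10, and adjusted p 0.381 with an estimated correlation), including Irf7 (6.51 ± 0.0165 to 31.6 ± 0.404 CPM). Of 23 inflammasome and NF-kB cytokine genes 22 were higher with a median of 2.28 (camera adjusted p 2.10e-08, and adjusted p 0.495 with an estimated correlation), including the adhesion gene Icam1 (14.3 ± 0.0269 to 58.1 ± 3.75 CPM). All 7 genes of MHC class II presentation were higher with a median of 2.43 (camera adjusted p 0.000537, and adjusted p 0.618 with an estimated correlation), and of 13 complement genes 11 were higher and 2 lower with a median of 1.84 (camera adjusted p 0.00532, and adjusted p 0.618 with an estimated correlation). The invariant chain gene Cd74 went from 139 ± 9.21 to 1016 ± 82.7 CPM and the central complement gene C3 from 8.22 ± 0.309 to 314 ± 8.94 CPM.

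Genes of the S1 and S2 segments and of the thick ascending limb were lower, and the other segment lists were either not called or lost their call in some settings. All 13 proximal tubule S1 and S2 genes were lower with a median of -1.45 (camera adjusted p 1.65e-05, and adjusted p 0.618 with an estimated correlation). The phosphate carrier Slc34a3 went from 28.1 ± 2.42 to 1.48 ± 0.590 CPM, the glucose carrier Slc5a2 from 385 ± 4.25 to 51.1 ± 8.34 CPM and the amino acid carrier Slc6a19 from 313 ± 12.6 to 43.5 ± 8.69 CPM. Of 11 thick ascending limb genes 9 were lower and 1 was higher with a median of -1.01 (camera adjusted p 0.00861, and adjusted p 0.618 with an estimated correlation), and Egf, the growth factor made by that segment, went from 769 ± 38.3 to 101 ± 11.5 CPM. Among genes with a mean of at least 10 CPM the largest fall was that of Pvalb, for the calcium buffer parvalbumin of the distal convoluted tubule, at 87.2 ± 8.89 CPM in Control and 0.245 ± 0.158 CPM in Uox_KO (log2 fold change -8.46, adjusted p 1.3e-06). Others of the 10 largest falls, besides Slc34a3, Ren1 and 2 haemoglobin genes, were the carboxylesterase Ces1g at 60.6 ± 2.66 CPM in Control and 1.67 ± 0.319 CPM in Uox_KO, Clec2h at 57.9 ± 2.97 CPM in Control and 4.12 ± 1.06 CPM in Uox_KO, the nuclease Dnase1 at 1059.8 ± 51.8 CPM in Control and 76.3 ± 5.48 CPM in Uox_KO, Wfdc15b at 319 ± 40.5 CPM in Control and 26.3 ± 2.18 CPM in Uox_KO and Azgp1 at 156 ± 4.90 CPM in Control and 12.9 ± 0.736 CPM in Uox_KO. Of 9 distal convoluted and connecting tubule genes 5 were lower (median -0.73, camera adjusted p 0.0431, and adjusted p 0.690 with an estimated correlation), and of 7 intercalated cell genes 6 were lower (median -1.58, camera adjusted p 0.0324, and adjusted p 0.684 with an estimated correlation). With the same spot number per region in each section, the distal convoluted list had a median of -0.42 and the intercalated list -0.80. Their camera adjusted p were 0.241 and 0.127. Without Control replicate 2 these were 0.0703 and 0.0604, and without Uox_KO replicate 1 the distal convoluted list was at 0.158. Without fat and injury spots the 2 adjusted p were 0.151 and 0.0784, with medians of -0.42 and -0.999. Without fat spots alone the distal convoluted list was at 0.0562 (median -0.61). Of 9 principal cell genes 4 were lower (adjusted p 0.186), of 11 proximal tubule S3 genes 6 were lower and 3 higher (adjusted p 0.388), and of 11 thin limb and inner medulla genes 8 were higher and 3 lower (adjusted p 0.0876).

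Transporters of urate and organic anions were mostly lower. Of 19 listed genes, 13 were lower and 4 were higher with a median of -0.74 (camera adjusted p 0.0117, and adjusted p 0.618 with an estimated correlation). The call also ended when each section gave the same number of spots per region (median -0.34, adjusted p 0.177) and without fat and injury spots (median -0.27, adjusted p 0.304). Slc22a12, for the urate reabsorber URAT1, was 761 ± 20.3 CPM in Control and 363 ± 7.63 CPM in Uox_KO (log2 fold change -1.07, adjusted p 2.7e-05). The organic anion carrier Slc22a8 went from 496 ± 25.6 to 138 ± 20.7 CPM, the phosphate and urate carrier Slc17a1 from 665 ± 19.8 to 315 ± 3.18 CPM and the lactate carrier Slc5a12 from 26.5 ± 3.13 to 4.56 ± 0.385 CPM. Among the exceptions, the efflux pump Abcc4 went from 20.8 ± 0.712 to 48.1 ± 5.58 CPM and Slco4c1 from 0.686 ± 0.0884 to 7.40 ± 4.08 CPM. Purine metabolism split, with 10 of 27 genes higher and 11 lower (adjusted p 0.686). The guanine deaminase Gda went from 5.95 ± 0.665 to 17.1 ± 0.832 CPM and the 5'-nucleotidase Nt5e from 32.5 ± 3.48 to 70.1 ± 5.74 CPM, and the synthesis gene Paics from 235 ± 10.2 to 145 ± 0.478 CPM and adenosine kinase Adk from 159 ± 12.9 to 87.4 ± 1.20 CPM. Xanthine dehydrogenase, Xdh, the enzyme that forms uric acid, went from 12.9 ± 0.498 to 19.1 ± 0.0855 CPM (adjusted p 2.9e-04), a call that ended with the same number of spots per region (adjusted p 0.113) and without fat and injury spots (adjusted p 0.0580).

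Genes of respiration, of kynurenine and NAD synthesis and of the male proximal tubule were lower in whole sections. None of 40 nuclear-encoded oxidative phosphorylation genes was higher and 33 were lower, with a median of -0.51 (camera adjusted p 1.34e-07, and adjusted p 0.618 with an estimated correlation). The nuclear RNA Malat1, chosen after its values were seen, went from 121 ± 25.9 to 266 ± 14.5 CPM in the same sections, and RNA quality was not separated from the fall of respiration genes here or in the regions. Of 13 mitochondrially encoded transcripts, 3 were higher and the list was not called (adjusted p 0.890). Of 10 kynurenine and NAD synthesis genes 9 were lower and 1 was higher with a median of -1.12 (camera adjusted p 0.00258, and adjusted p 0.495 with an estimated correlation). Of 11 male-biased proximal tubule genes 9 were lower and 2 were higher with a median of -1.48 (camera adjusted p 0.00469, and adjusted p 0.592 with an estimated correlation), and the steroid carrier Slco1a1 went from 422 ± 21.8 to 35.8 ± 5.05 CPM. Fatty acid oxidation and peroxisome genes split, with 14 of 33 higher and 15 lower (adjusted p 0.728), yet the omega-hydroxylase Cyp4a14 went from 21.8 ± 2.95 to 983 ± 11.8 CPM. Renin, Ren1, went from 107 ± 38.5 to 8.15 ± 1.32 CPM, while the renin-angiotensin list had 7 of 9 genes lower and 1 higher (adjusted p 0.0760).

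Genes of blood, fat and the lining of the urinary tract also separated the genotypes. All 5 red blood cell genes were lower with a median of -3.42 (camera adjusted p 0.0229, and adjusted p 0.618 with an estimated correlation). The haemoglobin genes Hbb-bs and Hba-a1 went from 2684 ± 118 to 199 ± 143 CPM and from 1359.7 ± 62.2 to 103 ± 72.9 CPM, and reads of haemoglobin paralogs can be shared. All 7 adipocyte genes were higher with a median of 5.89 (camera adjusted p 0.00723, and adjusted p 0.618 with an estimated correlation). All 7 urothelium genes were higher with a median of 8.79, or 8.71 with the 3 genes that had 0 counts in Control at their bound (camera adjusted p 0.000375, and adjusted p 0.495 with an estimated correlation). These tissues lie at the hilum and pelvis, so the lists also hold where each kidney was cut. Spots of fat numbered 5 and 18 in Control and 239 and 209 in Uox_KO. Without them 5523 genes were higher and 5295 lower.

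Of the stress lists, 2 were called higher. Of 15 immediate early genes 11 were higher and 3 lower with a median of 1.61 (camera adjusted p 0.0117, and adjusted p 0.495 with an estimated correlation). Of 13 p53 targets 10 were higher and 2 lower with a median of 0.62 (camera adjusted p 0.0117, and adjusted p 0.495 with an estimated correlation). Not called were oxidative stress and NRF2 genes with 11 of 26 higher and 6 lower, heat shock genes with 4 of 13 higher and 4 lower, and endoplasmic reticulum stress genes with 7 of 15 higher and 5 lower. The same held for cholesterol synthesis (7 of 18 higher, 5 lower), glycolysis and gluconeogenesis (5 of 20 higher, 8 lower), the circadian clock (3 of 16 higher, 6 lower), and calcium, phosphate and vitamin D (4 of 15 higher, 6 lower). It held too for urine concentration transport (3 of 18 higher, 8 lower), the osmolyte and NFAT5 response (4 of 8 higher, 2 lower), endothelial cells (1 of 10 higher, 6 lower), the glomerulus (2 of 12 higher, 8 lower) and the adrenal cortex (2 of 4 higher, 1 lower). Their adjusted p ran from 0.0756 to 0.882. In the purine, fatty acid, glycolysis, heat shock, urine concentration and S3 lists the mean was above 0 and the median below, and in the B and plasma cell list the test leaned down with both above 0. The genes beside Uox on its chromosome had 1 of 6 higher and 3 lower (adjusted p 0.201). The list was called lower in the distal region, with 3 of 6 genes lower (median -0.54, camera adjusted p 0.0412, and adjusted p 0.555 with an estimated correlation), and in the glomerular region, with 3 of 4 lower (median -0.99, camera adjusted p 0.0407, and adjusted p 0.333 with an estimated correlation). Without Uox_KO replicate 1 these calls ended (adjusted p 0.145 and 0.0724), as did the distal one without Control replicate 2 (adjusted p 0.0607) and the glomerular one without Uox_KO replicate 2 (adjusted p 0.154) and with the replicate number as a block (adjusted p 0.0504). Of the genes that differ between C57BL/6 substrains only Wdfy1 was tested, with a log2 fold change of -0.39 (edgeR adjusted p 0.0029). Nnt, whose symbol stands for 2 gene IDs, was not analysed. Adjusted over the list alone, the counts were the same in every list but 3: mitochondrially encoded transcripts had 2 higher, glycolysis 6 higher and 9 lower, and B and plasma cells 2 higher and 1 lower.

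**Figure D2:**
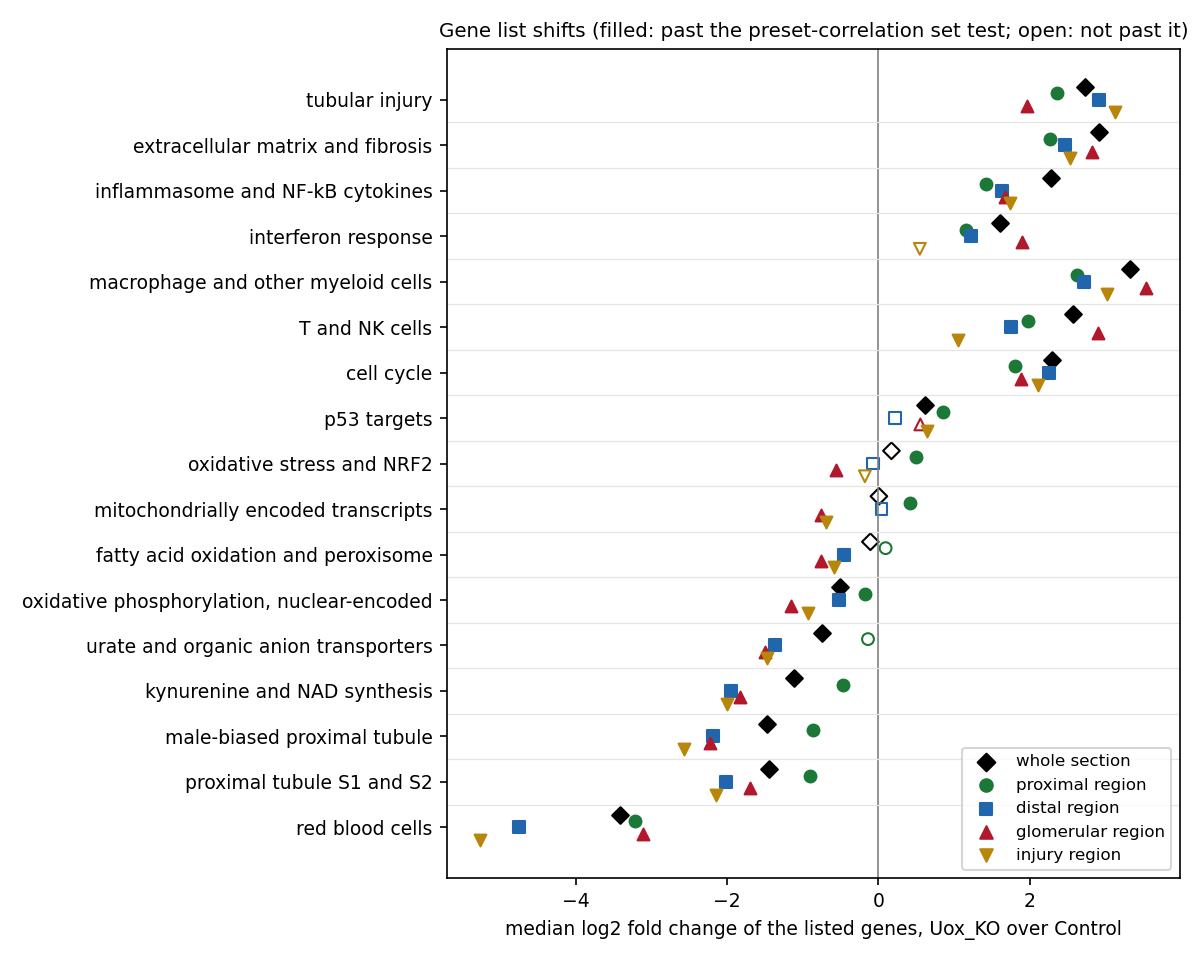
Median log2 fold change, Uox_KO over Control, of 17 gene lists in the whole section and in 4 regions, with filled symbols for lists past the set test with a preset correlation. Injury, matrix and myeloid lists lie above 0 in every comparison, and the S1 and S2, male-biased and red cell lists lie below 0 in every comparison.

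To ask where in the kidney these differences lie, spots were grouped into regions by clusters of expression named from marker genes. Proximal spots numbered 1407 and 1796 in Control and 1133 and 1102 in Uox_KO, distal spots 899 and 1213 against 291 and 393, glomerular spots 187 and 281 against 125 and 169, and injury spots 30 and 54 against 861 and 717. The clusters rest in part on genes that differ between the genotypes, so these numbers describe the regions and compare nothing. A clustering made without the genes called in whole sections was compared in their place. Those genes were left out by their calls in these same sections, and several of its clusters still held almost only spots of a single genotype. The genes that name its clusters were ranked over all genes, called ones included. Its shares thus do not separate the extent of a tissue from expression or depth per spot that differs between the genotypes. Its cluster led by Havcr1 and Aoc1 held 0.237% and 0.476% of the Control spots (95% exact intervals 0.0871 to 0.516% and 0.272 to 0.772%). In Uox_KO it held 12.6% of the spots of each section (11.4 to 13.9% and 11.3 to 13.9%). Its cluster led by the omega-hydroxylase Cyp4a14 and the protease inhibitor Serpina1d held 0.712% and 0.565% of the Control spots and 26.0% and 25.3% of the Uox_KO spots. Other clusters went the opposite way. The cluster led by Slc7a13 and Slco1a1 held 32.9% and 30.9% of the Control spots and 0.944% and 1.35% of the Uox_KO spots, and the cluster led by Slc5a2 and Slc6a19 held 27.1% and 25.6% against 4.23% and 4.90%. The exact two-sided permutation p was 0.333 for each cluster, the smallest that 2 against 2 sections allow.

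In the proximal region, injury, matrix and immune genes and antioxidant and cholesterol synthesis genes were higher in Uox_KO, and S1 and S2 genes were lower. The 2 genotypes fill this region with different clusters. Of 3203 Control spots, 3192 lay in clusters that hold mostly Control spots, and of 2235 Uox_KO spots, 2100 lay in clusters that hold mostly Uox_KO spots. A single cluster held 1747 of those Uox_KO spots. It had 0 markers among its 25 leading genes and counts as proximal only by its S1 and S2 levels. At the median these were 0.80 of the levels in clusters named proximal by markers. The distal clusters led by Pvalb, Klk1 and Aqp2 reached 0.88, 1.01 and 0.81, the one led by Calb1 0.34 and the glomerular cluster 0.84. Such levels are thus not particular to proximal spots. The differences below therefore also hold the makeup of segments. Of 14869 genes tested, 4314 were higher and 4076 were lower. Of 30 tubular injury genes 28 were higher and 1 was lower (median 2.37, camera adjusted p 2.10e-12, and adjusted p 0.594 with an estimated correlation), and Lcn2 went from 0.206 ± 0.0347 to 37.0 ± 4.47 CPM and Spp1 from 312 ± 19.2 to 5409 ± 631 CPM. Matrix genes were higher for 28 of 29 (median 2.27, adjusted p 0.594 with an estimated correlation) and myeloid genes for 24 of 26 (median 2.63, adjusted p 0.594 with an estimated correlation). Of the 78 genes of these 3 lists called higher here and at 10 CPM or more in the Uox_KO injury region, 76 had an excess over Control within 2-fold of 1 ratio, 17.4% of their level there, which mixed spots or spread RNA would also give. All 80 called genes of the 3 lists were still called after every section was thinned to the same total. The adipocyte genes were higher too (6 of 6, median 5.53, adjusted p 0.632 with an estimated correlation), at a small share of their level in fat.

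**Figure D3:**
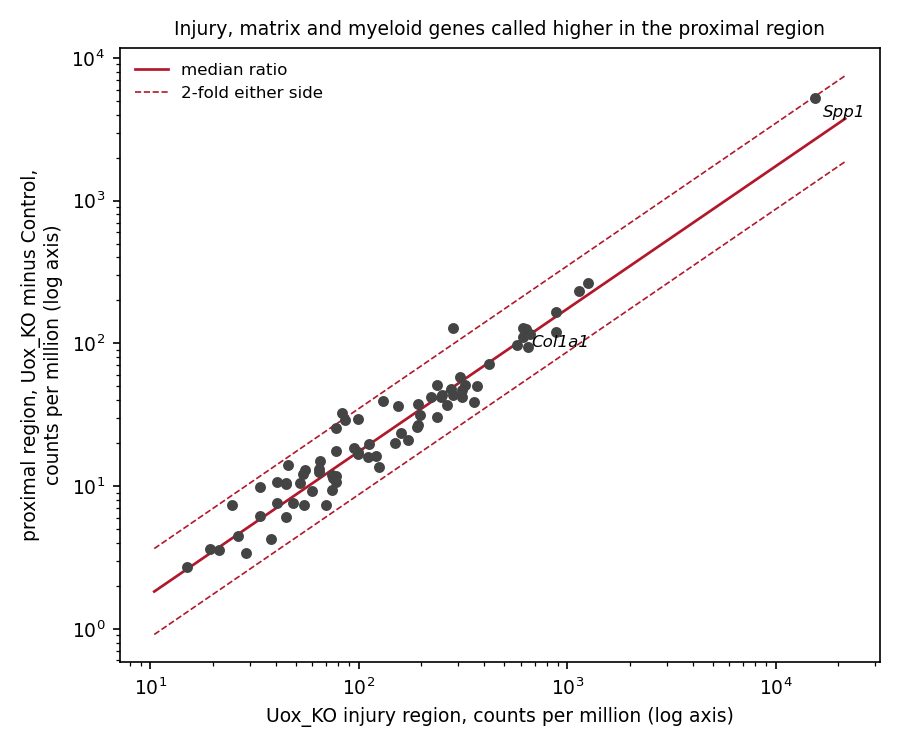
Each point is a tubular injury, matrix or myeloid gene called higher in the proximal region, with its Uox_KO injury-region level on the horizontal log axis and its Uox_KO minus Control difference in the proximal region on the vertical log axis, both in CPM. The solid line is the median ratio of 17.4% and the dashed lines are 2-fold either side, and 76 of 78 points lie between the dashed lines.

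Within this region the S1 and S2 genes were lower for 11 of 13 (median -0.91, camera adjusted p 0.000266, and adjusted p 0.632 with an estimated correlation), although several of them also lead clusters. The fall was not particular to them. Intercalated cell genes were lower for 7 of 7 (median -2.03, camera adjusted p 0.00687, and adjusted p 0.632 with an estimated correlation) and thick limb genes for 9 of 11 with 1 higher (median -1.06, camera adjusted p 0.00256, and adjusted p 0.632 with an estimated correlation). Distal convoluted genes were lower for 5 of 9 (median -1.03, camera adjusted p 0.0305, and adjusted p 0.654 with an estimated correlation). That call ended without Uox_KO replicate 1, where the median was -0.40. The cytokine signal inhibitor Cish went from 45.6 ± 1.73 to 3.73 ± 0.462 CPM (log2 fold change -3.61, adjusted p 7.4e-08). Oxidative phosphorylation genes were lower for 21 of 40 and higher for 2 (median -0.18, camera adjusted p 0.00465, and adjusted p 0.632 with an estimated correlation). Mitochondrially encoded transcripts were higher for 6 of 13 (median 0.42, camera adjusted p 0.0267, and adjusted p 0.659 with an estimated correlation). That call ended without Uox_KO replicate 2, where the median was 0.15, and without Control replicate 1, where it was 0.31. Of 25 oxidative stress and NRF2 genes 18 were higher and 2 lower (median 0.50, camera adjusted p 0.00176, and adjusted p 0.594 with an estimated correlation). The metallothionein Mt2 went from 26.0 ± 1.13 to 142 ± 15.7 CPM and haem oxygenase, Hmox1, from 19.4 ± 0.320 to 43.6 ± 2.68 CPM. Of 18 cholesterol synthesis genes 11 were higher and 2 lower (median 0.23, camera adjusted p 0.00502, and adjusted p 0.594 with an estimated correlation), with squalene epoxidase, Sqle, at 35.4 ± 0.119 CPM in Control and 129 ± 13.1 CPM in Uox_KO. Adjusted over the list alone, 18 NRF2 genes were higher and 3 lower, and the counts of the other lists named for this region were the same.

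The urate transporter list was not called in proximal spots, with 7 of 19 genes higher and 7 lower (median -0.14 with a mean above 0, adjusted p 0.524). It was called lower in the other 3 regions, with 14 of 18 genes lower and 3 higher in distal spots (median -1.37, camera adjusted p 0.000274, and adjusted p 0.555 with an estimated correlation) and 15 of 17 lower and 1 higher in glomerular spots (camera adjusted p 3.21e-05, and adjusted p 0.336 with an estimated correlation). In injury spots 15 of 18 were lower and 1 higher (median -1.47, camera adjusted p 9.49e-06, and adjusted p 0.360 with an estimated correlation). The S1 and S2 genes fell in the same distal, glomerular and injury spots, with medians of -2.02, -1.70 and -2.14. Less proximal tubule in these mixed spots was not separated from lower levels per cell. In proximal spots URAT1, Slc22a12, was 808 ± 4.30 CPM in Control and 573 ± 31.0 CPM in Uox_KO (log2 fold change -0.49, adjusted p 3.6e-04). There the efflux pump Abcc4 went from 19.1 ± 0.873 to 61.6 ± 5.93 CPM and Slco4c1, at 0.795 ± 0.0301 to 11.6 ± 5.72 CPM, also rose. The urate carriers Slc2a9 (log2 fold change -0.14, adjusted p 0.39) and Abcg2 (-0.14, adjusted p 0.14) did not pass the threshold. Of the purine genes in proximal spots, Gda (5.60 ± 0.311 to 16.4 ± 0.102 CPM) and Nt5e (32.7 ± 2.99 to 83.1 ± 3.63 CPM) were higher and the phosphorylase Pnp (148 ± 7.79 to 91.1 ± 5.96 CPM) was lower.

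In the distal region, which holds thick limb, distal convoluted tubule and collecting duct spots, Uox_KO spots carried more injury, matrix and immune transcripts, and proximal-type genes were lower. The cells that carry them were not told apart, since spots are mixed. Of 14495 genes tested, 3850 were higher and 3885 were lower. Of 30 tubular injury genes 29 were higher and 1 was lower (median 2.92, camera adjusted p 1.12e-13, and adjusted p 0.555 with an estimated correlation). Lcn2 was 0.430 ± 0.148 CPM in Control and 206 ± 75.1 CPM in Uox_KO. The simple-epithelium keratin Krt18 went from 16.4 ± 1.23 to 131 ± 3.50 CPM, haptoglobin, Hp, from 0.172 ± 0.0917 to 24.7 ± 4.82 CPM, and the growth factor binder Igfbp2 from 0.198 ± 0.180 to 23.1 ± 0.920 CPM, and the peptide hormone gene Cck had a log2 fold change of 6.86 (standard error 0.41). Cell cycle genes were higher for 17 of 18 (median 2.26, camera adjusted p 3.66e-08, and adjusted p 0.555 with an estimated correlation). Genes of urine concentration transport were higher for 12 of 17 and lower for 1 (median 0.72, camera adjusted p 0.00330, and adjusted p 0.555 with an estimated correlation), and principal cell genes for 6 of 9 (median 0.87, camera adjusted p 0.0158, and adjusted p 0.555 with an estimated correlation). Thin limb and inner medulla genes were higher for 8 of 10 and lower for 1 (median 2.18, camera adjusted p 0.00590, and adjusted p 0.555 with an estimated correlation). Matrix genes were higher for 28 of 29 (median 2.47, camera adjusted p 9.51e-12), myeloid genes for 26 of 26 (median 2.72, camera adjusted p 2.83e-11) and T and NK cell genes for 13 of 15 (median 1.75, camera adjusted p 8.25e-06), and S1 and S2 genes were lower for 13 of 13 (median -2.02, camera adjusted p 5.13e-07). The adjusted p of each of these 4 lists was 0.555 with an estimated correlation. The lists of the region's own segments were not called, with 5 of 11 thick limb genes higher and 4 lower (median 0.44, adjusted p 0.990), 3 of 9 distal convoluted genes higher and 2 lower (median -0.01, adjusted p 0.806) and 1 of 7 intercalated cell genes higher and 3 lower (median -0.04, adjusted p 0.743). Several genes of the transport and principal cell lists name the clusters, and each distal cluster held mostly spots of 1 genotype. Oxidative phosphorylation genes were lower for 34 of 40 (median -0.52, camera adjusted p 1.75e-07, and adjusted p 0.650 with an estimated correlation), and fatty acid oxidation genes for 22 of 33 with 6 higher (median -0.45, camera adjusted p 0.0198, and adjusted p 0.594 with an estimated correlation), a call that ended without Uox_KO replicate 1 (adjusted p 0.0631). Dnase1 went from 965 ± 67.8 to 46.7 ± 7.02 CPM and the tyrosine-degrading Hpd from 20.1 ± 0.542 to 0.963 ± 0.714 CPM. Adjusted over the list alone, 35 oxidative phosphorylation genes were lower, and 29 matrix genes and 9 thin limb and inner medulla genes were higher.

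In the glomerular region, whose spots also take in vessels and tubules around the glomeruli, macrophage and matrix genes rose, the glomerulus list was not called, and genes of respiration and of the tubule segments around fell. Of 12497 genes tested, 3454 were higher and 3422 were lower, or 2297 and 2277 with DESeq2. All 29 matrix genes were higher (median 2.82, camera adjusted p 1.56e-14, and adjusted p 0.293 with an estimated correlation), with the fibrillar collagen Col3a1 at 30.4 ± 4.28 CPM in Control and 495 ± 48.1 CPM in Uox_KO. All 25 tested myeloid genes were higher (median 3.55, camera adjusted p 3.60e-13, and adjusted p 0.293 with an estimated correlation), with the lysozyme Lyz2 at 34.6 ± 3.08 CPM in Control and 663 ± 63.5 CPM in Uox_KO. The T and NK cell genes were higher for 15 of 15 (median 2.90, camera adjusted p 3.79e-07, and adjusted p 0.293 with an estimated correlation). The acute-phase gene Serpina3n had 0 counts in Control and was at least 129-fold higher, and Hpd had 0 counts in Uox_KO and was at least 20.4-fold lower, each against 3 counts over the group. Contractile genes of smooth muscle and pericytes were higher for 8 of 8 (median 1.56, camera adjusted p 0.000237, and adjusted p 0.293 with an estimated correlation), with actin, Acta2, at 76.3 ± 4.35 CPM in Control and 400.2 ± 78.5 CPM in Uox_KO. Of 12 glomerulus genes 5 were higher and 3 lower, and the list was not called (adjusted p 0.902). Several of those genes define the cluster, and of the others the podocyte actin organizer Synpo went from 79.0 ± 3.55 to 179.9 ± 21.6 CPM. Tubule genes were lower too, with S1 and S2 genes for 13 of 13 (median -1.70, camera adjusted p 3.79e-07, and adjusted p 0.293 with an estimated correlation) and thick limb genes for 9 of 11 (median -1.74, camera adjusted p 8.35e-05, and adjusted p 0.293 with an estimated correlation). Distal convoluted genes were lower for 8 of 9 (median -1.47, camera adjusted p 0.000617, and adjusted p 0.388 with an estimated correlation) and intercalated cell genes for 6 of 7 (median -1.63, camera adjusted p 0.00895, and adjusted p 0.347 with an estimated correlation). Urine concentration transport was lower for 14 of 16 and higher for 2 (median -1.41, camera adjusted p 0.000665, and adjusted p 0.379 with an estimated correlation) and principal cell genes for 7 of 8 with 1 higher (median -1.35, camera adjusted p 0.0117, and adjusted p 0.437 with an estimated correlation), where both lists were called higher in distal spots. Oxidative stress and NRF2 genes, called higher in proximal spots, were lower here for 14 of 23 and higher for 4 (median -0.56, camera adjusted p 0.0262, and adjusted p 0.336 with an estimated correlation), a call that ended without Uox_KO replicate 2 (adjusted p 0.0804). Malat1, chosen after its values were seen, was 162 ± 55.3 CPM in Control and 591 ± 76.2 CPM in Uox_KO, and the median spot of this region had 24108 and 21855 UMIs in Control and 6562 and 8628 UMIs in Uox_KO. All 40 oxidative phosphorylation genes were lower (median -1.16, camera adjusted p 2.58e-13, and adjusted p 0.293 with an estimated correlation), and mitochondrially encoded transcripts were lower for 11 of 13 (median -0.76, camera adjusted p 0.00394, and adjusted p 0.506 with an estimated correlation). Adjusted over the list alone, the counts of these lists were the same.

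The injury region compared few Control spots with many Uox_KO spots, so its values rest on thin Control totals. Of 13534 genes tested, 2812 were higher and 2715 were lower, and without Control replicate 2 these were 1638 and 1808. At a cluster resolution of 0.3 they were 4509 and 4269, and after thinning 3629 genes were called, 1779 of them higher. The interferon-induced GTPase genes Igtp and Iigp1 were lower, with Igtp at 191 ± 14.1 CPM in Control and 24.8 ± 2.92 CPM in Uox_KO and Iigp1 at 156 ± 14.3 CPM in Control and 23.8 ± 3.23 CPM in Uox_KO. The call of Iigp1 ended at the resolution of 0.3 (log2 fold change -0.04, adjusted p 0.751). The interferon list split here, with 13 of 30 genes higher and 12 lower (adjusted p 0.760), and 15 and 12 adjusted over the list alone. C1qb went from 47.7 ± 17.1 to 536 ± 18.6 CPM and Laptm5 from 34.4 ± 0.435 to 194 ± 3.80 CPM. The phagocyte receptor Trem2 had 0 counts in Control and was at least 19.8-fold higher, and the chemokine Ccl7 at least 19.5-fold higher, each against 3 counts over the group.

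All 29 matrix genes were higher (median 2.53, camera adjusted p 3.34e-11), myeloid genes for 23 of 25 (median 3.03, camera adjusted p 3.51e-10) and tubular injury genes for 28 of 30 (median 3.14, camera adjusted p 3.51e-10). The myeloid median was 2.90 with the 3 genes that had 0 counts in 1 genotype at their bound. The same 3 lists named the region, with 16 markers among the 25 leading genes of its cluster. Its spots were mostly Uox_KO, so the rise of these lists here is not independent of how the region was named. All 40 oxidative phosphorylation genes were lower (median -0.93, camera adjusted p 6.77e-15). With an estimated correlation the adjusted p of each of these 4 lists was 0.360. Tubule genes fell alongside, with S1 and S2 genes lower for 13 of 13 (median -2.14, camera adjusted p 6.67e-08), distal convoluted genes for 7 of 9 (median -2.08, camera adjusted p 0.000918) and intercalated cell genes for 6 of 7 (median -2.58, camera adjusted p 0.00337). The adjusted p of each of these 3 was 0.424 with an estimated correlation. Thick limb genes were lower for 9 of 11 and higher for 1 (median -1.75, camera adjusted p 5.33e-05, and adjusted p 0.360 with an estimated correlation). Urine concentration transport was lower for 14 of 16 (median -1.77, camera adjusted p 0.000373, and adjusted p 0.424 with an estimated correlation) and principal cell genes for 7 of 8 (median -1.97, camera adjusted p 0.00347, and adjusted p 0.461 with an estimated correlation). Over the list alone, 29 tubular injury and 24 myeloid genes and 1 urine concentration gene were higher, and the counts of the other 7 lists of this paragraph were the same.

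The regions shared much of the difference. Of 12341 genes tested in all 4 regions, 1705 were higher and 1510 were lower in each of them, and 532 were called in opposite directions in some pair of regions. The regions come from the same sections, so they are not independent repeats. In a joint model with mouse as a block, the Uox_KO against Control difference itself differed between regions for 5827 of 15177 genes by edgeR's quasi-likelihood test. Between distal and proximal spots it differed for 3792 genes, of which 1473 were higher and 2319 lower in the distal difference.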

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

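The test of differences between regions and the thinning were planned. The tests of RNA spread and of the share of genes still called after thinning were chosen after the result was seen.

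The region by genotype test picked out 5827 of 15177 genes whose Uox_KO against Control difference differed between regions. Between the proximal and the distal region, 237 of them were called in opposite directions, 83 higher and 154 lower in the distal region than in the proximal one. The genes named here were chosen after their values were seen, leaving out genes that lead a cluster or mark a tubule segment. The differences below are distal minus proximal log2 fold changes.

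Tmem45b had a difference of 2.14, with a log2 fold change of -1.67 in proximal and 0.43 in distal spots (adjusted p 1.0e-13 by edgeR's quasi-likelihood test). The junction gene Cldn8 had a difference of 1.62 (-0.91 and 0.66, adjusted p 4.4e-15) and the potassium channel gene Kcnq1 one of 1.47 (-0.71 and 0.72, adjusted p 2.4e-13). These 3 genes were more abundant in distal than in proximal Control spots, with 33.7, 109.0 and 61.7 CPM against 18.2, 26.0 and 14.5 CPM. Other genes went the opposite way, and of these Acot3 was also more abundant in distal than in proximal Control spots, at 22.1 against 10.4 CPM. The acyl-CoA thioesterase Acot3 had a difference of -1.83 (1.52 and -0.37, adjusted p 4.2e-13), the peroxisomal Acnat2 one of -1.52 (0.26 and -1.31, adjusted p 1.6e-12) and the thiamine carrier Slc19a3 one of -1.40 (0.45 and -1.01, adjusted p 4.3e-08). The 2 genotypes fill the proximal region with different clusters, and 164 of 291 and 255 of 393 distal Uox_KO spots lay in a cluster with 0 and 2 Control spots. That was not separated from a change within cells.

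Fat spots were part of the whole-section sums and were not tested as a region. They numbered 5 and 18 in the Control sections and 239 and 209 in the Uox_KO sections. In Uox_KO fat spots Cfd was at 11673 CPM, Fabp4 at 11193 CPM and the brown fat gene Ucp1 at 2526 CPM. Uox_KO fat spots also held the urothelial genes Upk3a at 230.0 CPM and Krt5 at 122 CPM.

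Adipocyte genes were higher in Uox_KO in each of the other regions. In the proximal region 100% of the 6 called genes were still called after thinning, so lower summed counts alone did not make these calls. Spots were put into regions before the thinning, so effects of lower depth per spot were not tested. RNA spread from fat may be the source, since 100% of the 23 excesses, over genes and regions, lay within 2-fold of the median ratio of their region to the fat level. The single excesses were 1.12% of the fat level at the median and ran from 0.676% to 8.50%. By region the median ratio, as a fraction of the fat level, was 0.00930 in proximal, 0.0120 in distal and 0.00807 in injury spots. In glomerular spots it was higher, at 0.0537. Other genes called higher were not compared with fat in this way. Fat cells inside mixed spots would give the same ratio, and a genotype difference in perirenal fat was not tested.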

How the results depend on the processing

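Whole sections without fat spots, and without fat and injury spots, were settings chosen after the result was seen, and the others were planned. Whole sections gave 8915 called genes, without Control replicate 2, to 11135, without the low-count filter, against 10990. Without fat spots 10818 were called, 10312 of them also called with them, and without fat and injury spots 9098, of which 8502. The replicate number as a block gave 11116 called genes, 10792 of them also called without it, and the numbers do not pair the mice. The replicate 1 minus replicate 2 differences of Control and those of Uox_KO had a correlation of 0.0899 over genes in whole sections. In the regions most counts stayed within 1.5 times. In the glomerular region DESeq2 called 4574 genes (2297 higher, 2277 lower) against 6876, and thinning left 2272 lower against 3422. In the injury region thinning left 3629 called genes (1779 higher) against 5527, a resolution of 0.3 gave 8778 (4509 higher, 4269 lower), and leaving out 1 section gave 3446 to 4785 (1638 to 2425 higher, 1808 to 2360 lower), lowest without Control replicate 2. Fewer counts lower the thinned values by construction, and the cause of the others was not tested.

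The estimated correlation called 0 lists in whole sections and 0 in each of the 4 regions. The preset one called 23, 26, 23, 31 and 30, and fry called 29, 28, 25, 33 and 30. In whole sections the interferon and tubular injury lists had estimated correlations of -0.0308 and 0.00524, below the preset 0.01. Their unadjusted camera p still went from 1.77e-11 to 0.0167 and from 1.43e-12 to 0.0173. A higher correlation thus did not end these 2 calls. The estimated version also rests on the few residual degrees of freedom that 4 sections leave, which alone can end a call. For the other lists, gene correlation and the few sections were not separated. Under fry, heat shock in whole sections (median -0.0326, adjusted p 0.0466) and the genes beside Uox in the injury region (median -0.25, adjusted p 0.0362) leaned up where camera leaned down. Among single lists 177 results by setting lost their call and 51 gained one. The 177 include every list that the preset correlation called, each lost under the estimated one.

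Differences in the share of spots, Uox_KO minus Control in points, depended on the clustering. Proximal was -11.9 and became -13.3 at resolution 0.3, 1.82 without z-scoring, which reversed it, -2.24 with at least 2000 UMIs and -27.5 without called genes. Distal was -22.7 and became -15.3 at resolution 0.3, -17.2 at 0.8, -39.8 without z-scoring, -31.8 with at least 2000 UMIs and -15.8 without called genes. Glomerular was -2.26 and became -4.10 at 0.8 and -7.38 without z-scoring, and injury was 28.7 and became 20.4 at 0.3 and 36.9 without z-scoring. The cause was not tested. Gene tests were not run for the proximal region at 0.8 and the injury region without called genes, where a cluster led with more markers of another class. Nor were they for the injury region without z-scoring and the glomerular region at 0.3, without z-scoring or without called genes, where a section had under 20 spots.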

Other observations

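The genes of this and the next paragraph were chosen after their values were seen. Liver-type fibrinogen genes rose in the kidney, with Fgg at 6.46 ± 0.634 CPM in Control and 90.4 ± 16.3 CPM in Uox_KO and Fga at 8.02 ± 0.870 CPM in Control and 61.6 ± 5.24 CPM in Uox_KO. The growth factor gene Igf1 went from 2.76 ± 0.198 to 15.3 ± 1.57 CPM. The nephron transcription factor gene Hnf4a went from 279 ± 13.3 to 148 ± 10.7 CPM.

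Malat1, a nuclear RNA, went from 121 ± 25.9 to 266 ± 14.5 CPM and the ribosomal-repeat transcript Gm42418 from 495 ± 159.7 to 2043 ± 391 CPM. In distal spots Malat1 was 136 ± 27.3 CPM in Control and 271 ± 14.3 CPM in Uox_KO and in injury spots 146 ± 29.8 CPM in Control and 307 ± 7.53 CPM in Uox_KO. In the clustering without called genes, the cluster led by Gm42418, Lars2 and Malat1 held 2.77% and 3.69% of the Control spots and 16.4% and 15.4% of the Uox_KO spots, with a median of 5443 and 6613 UMIs per spot in Uox_KO.

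The thinning, camera and fry were planned. The tests below of 1 ratio, of the share of genes still called after thinning, of spans, of medians between lists and of shares of called genes were chosen after the result was seen. Injury, matrix and myeloid genes were higher in proximal spots of Uox_KO. Lower summed counts alone did not make these calls, since 100% of the 80 called genes were still called after thinning. Thinning came after the spots were put into regions, so effects of lower depth per spot were not tested. RNA spread from the injury region may contribute, since the excess of 97.4% of the genes lay within 2-fold of 1 ratio, 17.4% of the injury level, with a range of 10.6% to 45.0%. The same held for 86.7% of 2911 other genes called higher there, so the ratio is not special to these lists. Small injured patches inside proximal spots would give 1 ratio as well, and spot positions were not used here.

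S1 and S2 genes were lower in whole sections, with a median of -1.45. Within proximal spots the median was -0.91, but the 2 genotypes fill that region with different clusters, so fewer S1 and S2 spots and a lower level per tubule cannot be told apart here. Lower section totals alone did not make these calls, since 100% of the 13 called genes were still called after thinning. The thinning evens section totals only, so other effects of lower depth per spot were not tested. Mixing with other cells inside spots stays open too.

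Red cell genes were lower in every region. If less blood were the cause, the 5 genes would fall by 1 amount, and within a region their log2 fold changes spanned 0.77 to 1.12. That span passes the 1 set for a single source in at least 1 region and stays under the 2 set to exclude it, so less blood and another cause cannot be told apart here. How the kidneys were bled or perfused is not given in the sources used here.

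Male-biased proximal genes fell in proximal spots, which might point to a loss of androgen-dependent expression. Their median differed from that of the S1 and S2 list by 0.0413 on the log2 scale, so they fell no further than that list there. Genes of both lists lead proximal clusters that hold mostly Control spots. The comparison thus does not separate a specific fall from the makeup of the region. The S3 list had a median of 0.0246 in proximal spots against -0.87 for the male-biased list. Of its 11 genes 5 were higher and 5 lower, so a specific fall against S3 genes stays open. In glomerular spots the medians of the male-biased and the S1 and S2 lists were -2.23 and -1.70. In injury spots they were -2.57 and -2.14, so a specific fall in those regions stays open. Pdk4 was higher in proximal spots, which might point to a rise of fatty acid oxidation as a group. Of the 33 listed genes 48.5% were called higher there, against 29.0% of all genes tested in the region, and 11 were lower. The list was not called by camera (adjusted p 0.192) and was called up by fry (adjusted p 0.0139), so a rise of the group and of some members alone cannot be told apart here.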
